A study of Mus musculus with 2 samples.

How the data were processed

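RNA-seq values of 2 libraries of untransformed mouse myeloid progenitors were analysed. Per the labels' protocols, bone marrow cells depleted of lineage-positive cells were grown for 7 days with interleukin 3, stem cell factor and interleukin 6, total RNA was purified on RNeasy columns with DNase treatment on the column, and libraries were made with the TruSeq RNA kit. The authors deposited a table of RPKM values with 1 column per library. The submitters' processing notes name Trimmomatic 0.32 (read trimming), TopHat2 (spliced alignment), HTSeq (counting) and edgeR, with the mouse genome build mm9. Their settings, the annotation, the strand setting and the library size used for the RPKM values are not given in the sources used here. The columns were assigned to replicate 1 and replicate 2 by their names, which match the sample titles.

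The table had 24015 rows. Of these, 27 carried names in the form of dates (such as a day and a month), held 0.109% of the summed RPKM in each library and were left out, which left 23988 genes, 7211 of them at 0 in both libraries. Gene names were used as deposited. Of these, 22508 are current symbols in RefSeq annotation of assembly GRCm38.p6, 1341 older symbols and 139 neither. Because that assembly differs from the authors' build, no coordinates are given. RPKM divides reads by gene length and library size. It allows comparison of genes only as far as the lengths used, which are not given, are those of the genes. A few very high genes can lower the values of all others in a library. Copies of near-identical genes (haemoglobins, Mcpt and Ear genes, histones) can lose or share reads in counting. An exact 0 is reported as listed at 0, since Hmgcs1, a gene of cholesterol synthesis in most cells, was also at 0.

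Depth was read from the steps between RPKM values. The ratio of the effective library sizes, replicate 2 over replicate 1, was 0.962, the value shared by 474 genes with equal read numbers in both libraries (tolerance 1e-05). The scale came from 50 genes of 1468 tried, each with 1 annotated transcript in GENCODE vM21, which gave the same value (tolerance 1e-06). It put the effective sizes at 29941063 and 28793666 reads. These may be read totals multiplied by a normalisation factor, which the table cannot separate, so neither they nor their ratio are sequencing depth as such. At these sizes 100% of the 16777 genes above 0 gave whole reads in both libraries at some length, within a tolerance of at most 0.0029 reads that follows the rounding of the table. Of the 14187 genes above 0 in both libraries and under 200 RPKM in sum 100% did, against 9.42% of 998 shuffled pairs of such values. The read numbers given are the smallest that fit. The smallest fitting length was 5806 bp for Bnip3, 4459 bp for Nkg7 and 2808 bp for Tpsb2. Such lengths may exceed the transcripts, so the lengths used and the scale remain uncertain. Ratios of read numbers carry 95% intervals that cover counting error only, since the reads have no molecular identifiers.

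All groups, gene lists, contrasts and named genes were fixed before the data were examined, except where stated. Each of the 40 gene lists was described by the median RPKM of its members in each library and by the number of members at 1 RPKM or more in both, which is called detected. The median of the mean RPKM was placed among 10000 random lists drawn from genes above 0. Differences between libraries were median log2 ratios of replicate 2 over replicate 1 with a pseudocount of 1, over members with a mean of 1 RPKM or more, placed among 10000 random lists matched on mean expression in 20 bins. Such ratios understate differences of low genes. The 10 contrasts between lists were differences of medians of log2(RPKM + 1) within each library, given as mean and SD over 2 libraries, and were called beyond the spread when both libraries had the same sign and the mean was over 2 SD. No test was run, because an exact sign-flip permutation test over 2 libraries cannot go below p = 0.5. Named genes were the 4 highest detected members of each list, the 10 highest of all genes, the 5 largest log2 ratios in each direction at a mean of 5 RPKM or more, any gene that a count of 5 or fewer refers to, and a preset group: Hoxa9, Hoxa10, Hoxa7, Meis1, Pbx3, Cebpa, Spi1, Kit, Il3ra, Csf2rb, Il6ra, Il6st, Flt3, Cd34, Myc, Csf1r and Csf3r. Some genes that this rule takes are not reported here. For a check of bias, medians of the log2 ratio in 50 bins of GC content and then of transcript length were subtracted, with sequences of the longest GENCODE vM21 transcript for 10840 of 10896 genes. Another 6 lists were added after the data were seen and appear only in the closing section.

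The comparison with random lists was tested on simulated data for differences between libraries, over 10783 genes. Of 5 simulated lists of 10 genes at a 1.5-fold difference, 5 lay outside the central 95% of random lists, as did 5 of 5 at 2-fold and 1 of 4 at 1.25-fold. Of 200 lists with no difference, 11 lay outside. The simulated genes varied independently of each other, with a fixed spread and a single length. That spread was smaller than the SD of 1 library seen in the data, so the recovery of simulated differences may be overstated. Members of real lists can move together, so this rate does not carry over to them. Alternatives were other pseudocounts, detection limits and filters, values rescaled to the same sum in each library (TPM scale), other scalings of the libraries, means in place of medians, and leaving out each library. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9 were used.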

Results

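The data came from untransformed mouse myeloid progenitors. Bone marrow cells of C57BL/6 mice were depleted of cells bearing lineage markers and grown for 7 days with interleukin 3, stem cell factor and interleukin 6. The series title concerns leukaemia cells driven by HOXA9 and MEIS1. The labels give 1 group of 2 libraries, here replicate 1 and replicate 2, and leukaemia cells were not analysed here. The question the data can answer is which programmes these untransformed cells expressed and how closely the 2 libraries matched. Values are RPKM, read numbers divided by gene length and library size, for 23988 genes. The steps between low values placed the effective library sizes at 29941063 reads in replicate 1 and 28793666 in replicate 2, sizes that may include a normalisation factor. A single read in a gene of 1 kb was thus worth 0.0334 and 0.0347 RPKM, and the limit that a count of 0 allows, 3 reads, was 0.10 RPKM in each library to 2 digits. Nothing in the labels says whether the libraries came from separate cultures or animals, so the source of the spread between them is not known. With 2 libraries an exact sign-flip permutation test cannot go below p = 0.5, and no test was run.

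Among the cell type lists, the cells expressed the genes of neutrophil granules most strongly, with genes of monocytes, of macrophages and those shared by mast cells and basophils beside them. S100a9 and S100a8, which together form the calcium-binding protein calprotectin of neutrophils and monocytes, were the 2 highest of all genes. S100a9 stood at 26131 RPKM in replicate 1 and 18619 in replicate 2, and S100a8 at 17987 and 13323. The pair held 7.19% and 5.19% of the summed RPKM. The other genes among the 10 highest were Ftl1 (ferritin light chain), Tmsb4x (thymosin beta 4), Ngp (neutrophilic granule protein), Chil3 (a chitinase-like protein) and the ribosomal protein genes Rps3a1, Rps2, Rps3 and Rps24. These 10 genes held 15% and 12.3% of the summed RPKM. In all, 10445 genes reached 1 RPKM in both libraries, 10611 in replicate 1 and 11032 in replicate 2. Of the 39 lists with members in the table, 18 had a median level above the central 95% of random lists and 10 below. Without replicate 2 the first count was 14, since monocyte, macrophage, MHC class II and cytokine genes then lay inside. Against random lists of genes at 1 RPKM or more, 12 lay above and 17 below. The lower count was 4 with members at 0 left out, since the random lists held no gene at 0 in both libraries.

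The list of neutrophil primary granules, which are made at the promyelocyte stage, had the highest median among the cell type lists. It also holds genes whose products are not granule proteins, such as Ms4a3 and Igsf6. The list median was 299 RPKM in replicate 1 and 294 in replicate 2, and all 12 members were detected at 1 RPKM or more in both. Mpo (myeloperoxidase) stood at 1587 and 1164 RPKM, Elane (neutrophil elastase) at 1327 and 1087, Prtn3 (proteinase 3) at 1135 and 935, and Ctsg (cathepsin G) at 753 and 508. All 17 genes of secondary granules and late maturation found in the table were detected, with medians of 156 and 178 RPKM. Ngp reached 6247 and 7796 RPKM, and Chil3 9447 and 3725. Primary granule genes exceeded secondary granule genes by 0.74 ± 0.12 (SD, n = 2) on the log2(RPKM + 1) scale, which was more than 2 SD. The difference had the opposite sign, -0.56, when means replaced medians, and was 0.32 with the highest member of each list left out.

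Basophil genes were expressed in both libraries, whereas genes of mature mast cells were low in replicate 1. The 8 basophil genes had medians of 23.2 and 31.4 RPKM with 6 detected, inside the central 95% of random lists by level and above it without replicate 1 or with a mean of log2(RPKM + 1). The basophil proteases Mcpt8 and Prss34 stood at 668 and 324 RPKM in replicate 1 and at 1567 and 382 in replicate 2. Of the 12 genes that mast cells and basophils share, 11 were detected in both libraries, with medians of 33.9 and 39.1 RPKM, and Il13 was the exception. Fcer1g, a signalling chain of Fc receptors, stood at 589 and 476 RPKM, Cpa3 (carboxypeptidase A3) at 221 and 556, Cyp11a1 at 229 and 342, and the transcription factor gene Gata2 at 119 and 158. Only Mcpt2, Cma1, Slc18a2 and Mitf were detected in both libraries among the 13 mast cell genes, whose medians were 0.195 and 7.74 RPKM. Shared mast cell and basophil genes lay below primary granule genes, with a difference of -2.93 ± 0.16 (SD, n = 2). The difference between mast cell and basophil genes was -4.31 in replicate 1 and -1.89 in replicate 2, within 2 SD of 0. Of the 11 eosinophil genes, 8 were detected, among them Epx (eosinophil peroxidase) at 58.9 and 35.8 RPKM and Prg2 (major basic protein) at 36.7 and 30.6.

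Monocyte, macrophage and antigen presentation genes were expressed in both libraries and at higher levels in replicate 2. Monocyte genes had medians of 18.7 and 43.7 RPKM with 9 of 12 members detected, led by Ly6c2 at 611 and 871 RPKM. Macrophage genes had medians of 11.7 and 32.4 RPKM with 15 of 18 detected, led by Lyz2 (lysozyme) at 442 and 1853 RPKM and Ctsd (cathepsin D) at 461 and 730. MHC class II genes had medians of 11.6 and 41.8 RPKM with 8 of 10 detected, and those of MHC class I and antigen processing 44.8 and 72 RPKM with all 10 detected. Dendritic cell genes were lower, at 1.30 and 3.81 RPKM with 7 of 14 detected. The highest of these, Clec10a and Mgl2, are lectins that macrophages also express. Monocyte genes exceeded macrophage genes by 0.52 ± 0.15 (SD, n = 2), and this difference also turned negative, to -0.18, with means in place of medians.

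Genes of lymphoid cells, red cells and stroma were mostly below the detection limit, and the median levels of stem cell and megakaryocyte genes lay inside the central 95% of random lists, though below it against random lists of genes at 1 RPKM or more. Stem and early progenitor genes had medians of 2.46 and 3.46 RPKM with 13 of 19 detected, led by Lmo2, Myb, Tal1 and Cd48. Kit, the receptor of stem cell factor, stood at 21.2 and 26.2 RPKM and Cd34 at 14.5 and 19.5. Of the 15 B cell genes, Cd79b alone was detected, at 2.43 and 5.36 RPKM. Thy1, at 30.5 and 22.4 RPKM, and Il7r, at 3.90 and 9.36, were the detected members of 19 T and NK cell genes. Pdgfrb and Lepr, at 2 to 3 RPKM, were the detected members of 16 genes of stroma and endothelium. Stem and progenitor genes exceeded B cell genes by 1.94 ± 0.21 and T and NK cell genes by 1.92 ± 0.21 (SD, n = 2), differences that were 4.65 and 4.44 with a pseudocount of 0.1. Gata1, Car2, Aqp1 and Gfi1b were the detected members of 19 erythroid genes, and primary granule genes exceeded this list by 7.79 ± 0.23 (SD, n = 2). The haemoglobin genes were listed at 0 in both libraries, where an exact 0 can be a counting failure because their copies share reads. Of the 15 megakaryocyte genes, 12 were detected, including Itgb3 at 54.2 and 40.6 RPKM and Pf4 (platelet factor 4) at 10.1 and 20.6. Xist, the RNA of the inactive X chromosome, stood at 139 and 172 RPKM, and no Y-linked gene of the list exceeded 0.00866 RPKM.

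**Figure D1:**
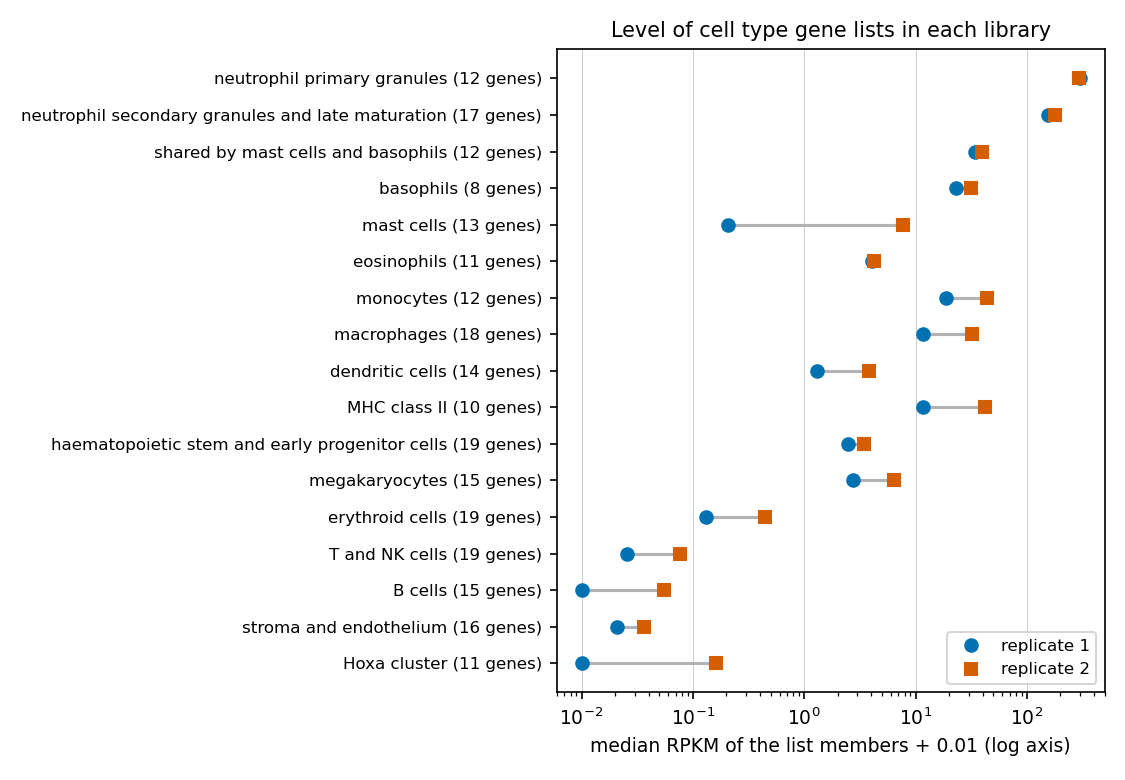
Median RPKM of the members of each cell type list in replicate 1 (circles) and replicate 2 (squares), with 0.01 added, on a log axis; grey lines join the 2 libraries. Neutrophil primary granule genes are highest at 299 and 294 RPKM, and mast cell genes lie farther apart, at 0.195 and 7.74 RPKM, than the other myeloid lists.

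The homeobox genes central to the leukaemia model were low in these cells, with the exception of Meis1. No Hoxa gene reached 1 RPKM in both libraries. Hoxa9 stood at 0.0342 RPKM in replicate 1 and 3.13 in replicate 2, which correspond to at least 2 and 176 reads. Hoxa7 was listed at 0 and at 0.845 RPKM, and Hoxa10 at 0 and at 0.112. Hoxb4, at 1.54 and 2.16 RPKM, was the detected member of the 10 Hoxb genes, and no Hoxc or Hoxd gene was detected. Meis1, which encodes a cofactor of HOXA9, stood at 11.2 and 10.9 RPKM, and its partner gene Pbx3 at 1.44 and 0.591. Pbx2 was the highest of the 11 TALE homeobox genes at 148 and 134 RPKM, and 6 of them were detected. The difference between Hoxa and Hoxb genes, 0.10 ± 0.14 (SD, n = 2), was smaller than the spread between libraries. It was 0.66 with a pseudocount of 0.1 and -0.24 with members at 0 left out, so its direction is not settled. Of 15 genes linked to HOXA9 and MEIS1 in leukaemia, 14 were detected, with medians of 11.4 and 13 RPKM. The exception was the receptor gene Flt3, at 0.0904 and 1.11 RPKM. Pim1, a kinase gene induced by cytokines, led this list at 246 and 483 RPKM, and Myc stood at 75.8 and 91.5.

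The haematopoietic transcription factor genes were well expressed in both libraries. Their medians were 42.7 and 49.6 RPKM, and 34 of 35 were detected, Gata3 being the exception. Cebpa, needed to form granulocyte and monocyte progenitors, stood at 61.3 and 66.3 RPKM, and Spi1, which encodes PU.1, at 77.2 and 70.5. Cebpe, a regulator of secondary granule genes, stood at 156 and 131 RPKM, and Lyl1 at 226 and 204. Chromatin regulators had medians of 23.9 and 21.3 RPKM with 27 of 28 detected, led by Hdac1 at 522 and 451.

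All 6 genes for receptors of the culture cytokines were detected, with medians of 17.1 and 25.4 RPKM. Csf2rb, the common beta chain, was by far the highest at 343 and 497 RPKM. Il3ra stood at 13.1 and 22.3 RPKM, Il6ra at 11.5 and 24.5, and Il6st, the signalling chain for interleukin 6, at 12.4 and 22.4. Among 15 genes for other haematopoietic cytokine receptors, 10 were detected. Csf2ra stood at 283 and 263 RPKM, Csf3r at 120 and 148, and Csf1r at 22.0 and 71.0. Culture cytokine receptors minus the others gave -0.89 ± 0.73 (SD, n = 2), within 2 SD, and 1.13 with means in place of medians. Of 17 genes of the STAT pathway and its targets, 16 were detected, with Pim1, Mcl1 (a survival factor), Jak1 and the feedback gene Cish highest.

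The cultures expressed proliferation genes strongly. G1/S genes had medians of 83.0 and 57.9 RPKM with 19 of 20 detected, the exception being Ccnd1 (cyclin D1) at 0.765 and 4.74 RPKM. Rrm2, a subunit of ribonucleotide reductase, led at 409 and 277 RPKM. All 16 G2/M genes were detected, with medians of 75.7 and 60.7 RPKM, including Mki67 at 164 and 140 and Top2a at 155 and 143. Of 7 genes for inhibitors of cyclin-dependent kinases 6 were detected, led by Cdkn1a (p21) at 52.0 and 105 RPKM. G2/M genes exceeded the inhibitors by 2.44 ± 0.69 (SD, n = 2).

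Housekeeping and metabolic lists were high. Ribosomal protein genes had medians of 920 and 1008 RPKM with 81 of 85 detected, and the 11 reference genes 440 and 410 RPKM, Actb standing at 993 and 971. All 15 glycolysis genes were detected, with medians of 105 and 298 RPKM. Cytokine and chemokine genes had medians of 9.89 and 24.3 RPKM with 18 of 24 detected, led by Ccl6 at 910 and 1600. Immediate early and stress genes had medians of 18.0 and 91.0 RPKM with 14 of 17 detected. Interferon response genes were low at 1.02 and 2.74 RPKM, with 8 of 16 detected. Replication-dependent histone genes had medians of 0.311 and 0.546 RPKM, with 11 of 68 detected. How RNA was selected for the libraries is not stated here, so these low values need not mean low expression. No symbol of a mitochondrially encoded gene was found in the table.

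The 2 libraries ranked genes alike but differed in distinct sets of genes. Across the 16777 genes above 0 in either library, Pearson's r of log2(RPKM + 1) was 0.981 and Spearman's rho 0.973, genes not being independent replicates. The SD of 1 library on that scale was 0.40 for genes from 1 RPKM, 0.37 from 5, 0.36 from 20, 0.45 from 100 and 0.37 from 500. The median log2 ratio of replicate 2 over replicate 1 was -0.049. Among 8151 genes with a mean of at least 5 RPKM, 344 were at least 2-fold higher in replicate 2 and 42 in replicate 1. At 8-fold the counts were 29 and 0. The difference has no replicate check, since each side is 1 library.

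**Figure D2:**
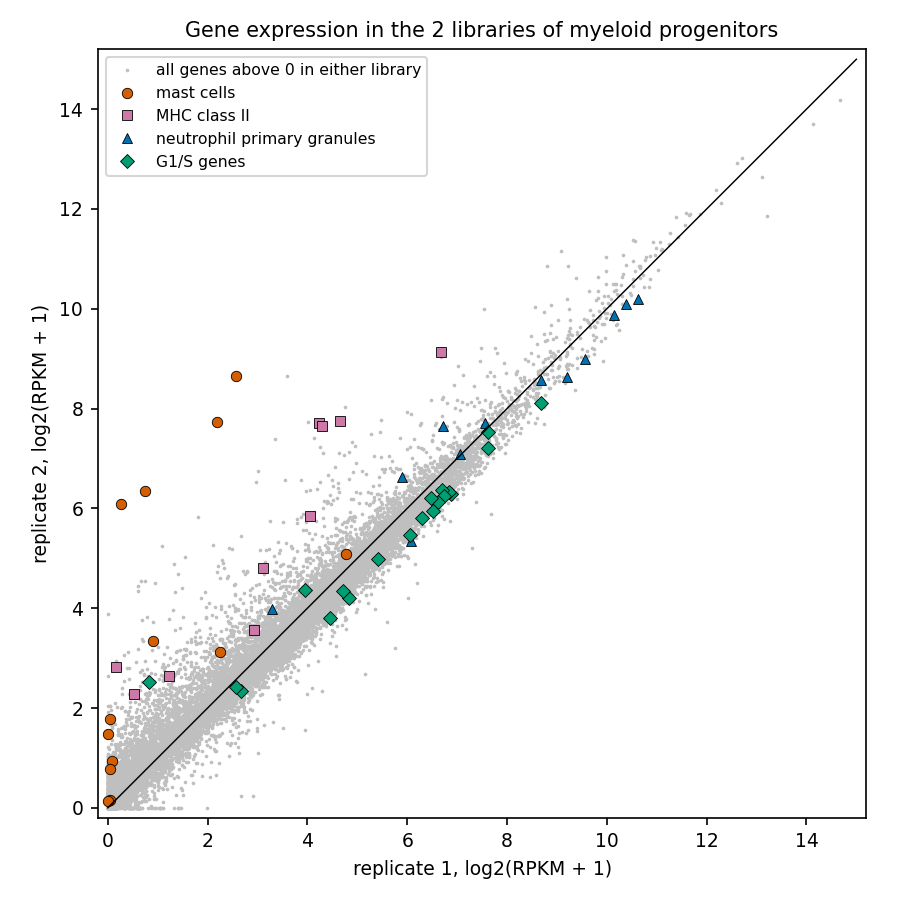
log2(RPKM + 1) of each gene in replicate 1 against replicate 2, with the line of equal values and 4 gene lists marked. Pearson's r is 0.981; mast cell and MHC class II genes lie above the line, with median log2 ratios of 3.99 and 2.13, and G1/S genes mostly below it, with -0.45.

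Mast cell protease genes were the most different, all higher in replicate 2. Mcpt2 stood at 4.97 RPKM in replicate 1 and 402 in replicate 2, Cma1 (mast cell chymase) at 3.55 and 211, Tpsb2 (a tryptase) at 0.666 and 80.9, and Mcpt4 at 0.195 and 67.0. These protease genes have close copies that may share reads, so the value of a single member is uncertain. The fifth gene of this group was Fn1 (fibronectin) at 11 and 401 RPKM. Among the genes most strongly higher in replicate 1 were Mid1 at 53.0 and 8.24 RPKM, Fam115a at 14.5 and 1.93, Clec4b2 at 156 and 35.9, and Hpgds (prostaglandin D synthase) at 18.7 and 4.08.

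Of the 31 lists with at least 3 members at a mean of 1 RPKM, 20 had a median log2 ratio above the central 95% of 10000 random lists matched on expression, and G1/S genes alone lay below. These ranges describe the 2 libraries and are no test of a difference between conditions. Some lists share members, such as Pim1 and Csf1r, so the counts are not of separate shifts. The random lists hold unrelated genes, whereas members of a list may move together and so leave the range more easily. The mast cell list had a median log2 ratio of 3.99 with all 8 members higher in replicate 2. The rise was uneven, with log2 ratios of 0.31 for Slc18a2 and 0.88 for Mitf against 5.54 for Cma1 and 6.08 for Mcpt2. The list median was 5.54 with a minimum of 5 RPKM and 5.05 with a pseudocount of 0.1. Over the 4 members with at least 100 reads in both libraries, a filter chosen after seeing the data, it was 3.21, between the values of Mitf and Cma1. MHC class II genes followed at 2.13, or 2.78 with that filter, with all 10 higher, including Cd74 (the invariant chain) at 102 and 560 RPKM and H2-Ab1 at 17.8 and 209. Monocyte genes stood at 1.73, with all 11 higher, including F13a1 at 25.9 and 262 RPKM and Ccr2 (a chemokine receptor) at 28.8 and 160. Macrophage genes stood at 1.04 with all 16 higher, dendritic cell genes at 1.13 with all 8 higher, and MHC class I genes at 0.63 with all 10 higher. Immediate early and stress genes stood at 1.42 with 11 of 15 higher. The 4 lower members were the chaperone genes Hspa8 and Hsp90aa1 and the stress factor genes Atf4 and Ddit3. Cytokine and chemokine genes stood at 1.07 with 20 of 22 higher, Ccl24 and Tgfb1 being lower. Glycolysis genes stood at 1.04, and 14 of 15 were higher, among them Pgk1 at 599 and 1854 RPKM, with Hk3 the exception.

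Smaller positive medians were found for megakaryocyte genes at 0.81, histone genes at 0.79, receptors of the culture cytokines at 0.72, shared mast cell and basophil genes at 0.63, inhibitors of cyclin-dependent kinases at 0.63, basophil genes at 0.45, STAT pathway genes at 0.41 and other cytokine receptors at 0.40. The lists of genes linked to HOXA9 and MEIS1, at 0.26, of secondary granules, at 0.19, and of ribosomal proteins, at 0.15, lay just above their ranges. The first of these lay inside its range with a mean in place of the median or a minimum of 5 RPKM, ribosomal proteins with a mean, and secondary granule genes, still at 0.19, with the trends on GC content and transcript length removed, a correction chosen after seeing the data. Secondary granule genes stood at 0.51 with a mean. Histone genes stood at 1.32 with a pseudocount of 0.1 and at 1.39 with a minimum of 5 RPKM, and other cytokine receptors at 0.68 with a pseudocount of 0.1 and at 0.62 with a mean. Megakaryocyte genes stood at 0.50 with members of at least 100 reads in both libraries. G1/S genes had a median log2 ratio of -0.45, with 18 of 20 lower in replicate 2, Ccnd1 and Ccnd2 being the exceptions, and stood at -0.29 with a mean. Primary granule genes at -0.19, eosinophil genes at 0.11, stem and progenitor genes at 0.11, transcription factor genes at 0.02, chromatin regulators at -0.12, interferon response genes at 0.08, TALE genes at -0.07, erythroid genes at 0.33 and reference genes at -0.08 lay inside their ranges. G2/M genes, at -0.27 with 15 of 16 lower, were inside as well. With a mean in place of the median, G2/M genes at -0.26 and TALE genes at -0.29 lay below their ranges and transcription factor genes at 0.28 above, while primary granule genes stood at -0.034, stem and progenitor genes at 0.25 and interferon response genes at 0.24. Scaling by the median ratio put chromatin regulators at -0.066, TALE genes at -0.030, reference genes at -0.025 and transcription factor genes at 0.075. With a minimum of 5 RPKM eosinophil genes turned to -0.25 and interferon response genes to -0.087. With members of at least 100 reads in both libraries, stem and progenitor genes turned to -0.034, interferon response genes to -0.16 and erythroid genes stood at 0.19, so eosinophil, stem and progenitor and interferon response genes had no settled direction.

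**Figure D3:**
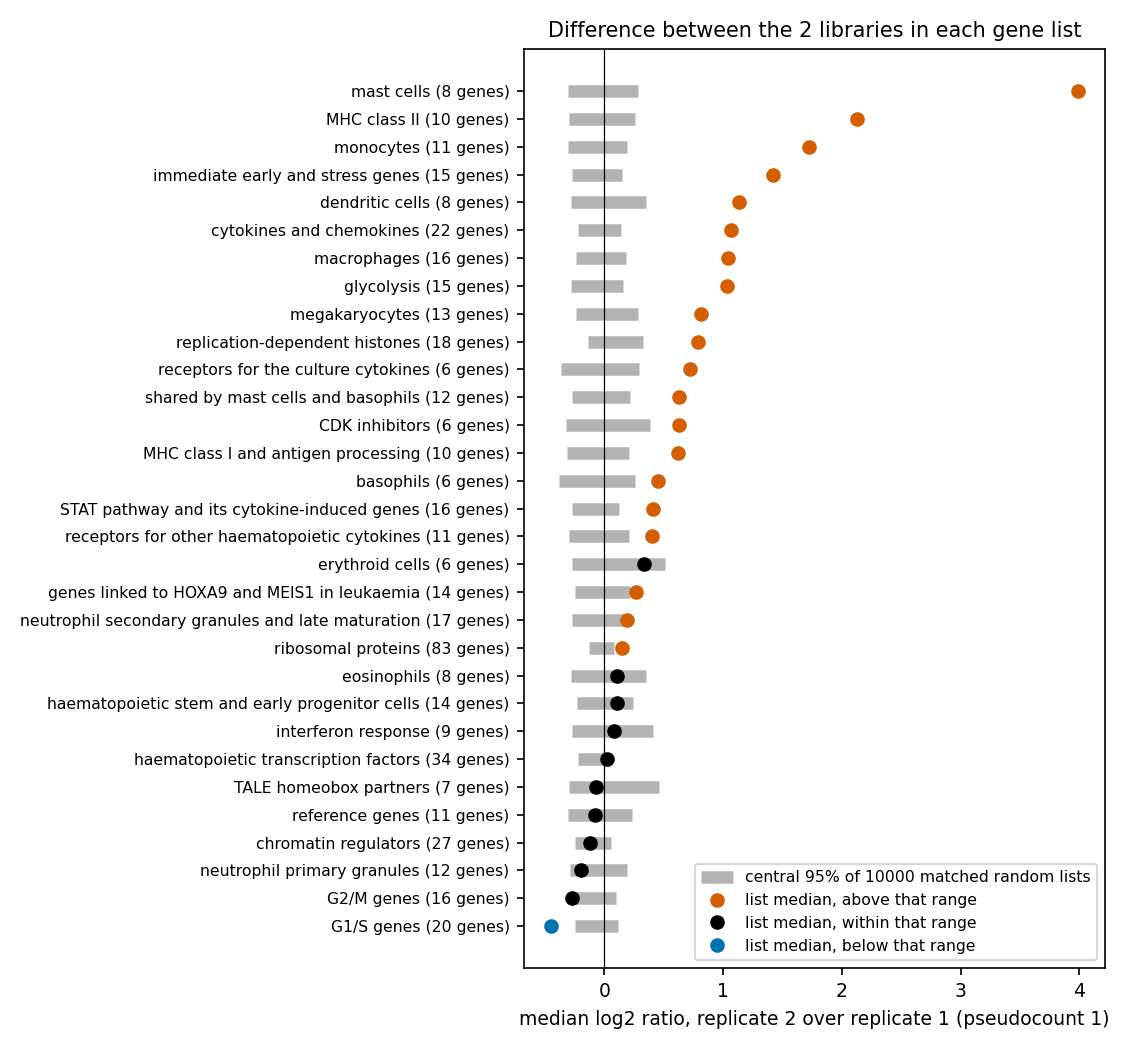
Median log2 ratio of replicate 2 over replicate 1 for each gene list (points) and the central 95% of 10000 random lists matched on mean expression (grey bars). Of 31 lists, 20 lie above their bar, the mast cell list farthest at 3.99, and the G1/S list alone lies below, at -0.45.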

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

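Alternatives were fixed before the data were examined, except the restriction to members with at least 100 reads in both libraries and the removal of trends on GC content and transcript length, chosen after seeing the data. The number of detected genes stayed within 1.5 times of 10445 under 6 alternatives, from 7758 at 5 RPKM to 11290 at 0.5 RPKM, with 10611 and 11032 when a library was left out. Pearson's r was 0.978 with a pseudocount of 0.1, 0.961 with 0.01, 0.960 over genes at a mean of 1 RPKM or more and 0.980 without the 100 highest genes. With a mean in place of the median, primary minus secondary granule genes reversed to -0.56 and monocyte minus macrophage genes to -0.18; shared mast cell and basophil minus primary granule genes gave -2.70, culture minus other cytokine receptors 1.13, stem cell minus B cell genes 2.41 and primary granule minus erythroid genes 6.93. A pseudocount of 0.1 gave 4.65 and 4.44 for stem cell minus B cell and minus T and NK cell genes, 9.67 for primary granule minus erythroid genes and 0.66 for Hoxa minus Hoxb genes. With members at 0 left out the last 2 were 7.44 and -0.24. Without the highest member of each list, primary minus secondary granule genes gave 0.32, shared mast cell and basophil minus primary granule genes -2.70, primary granule minus erythroid genes 7.33 and G2/M genes minus inhibitors 3.37. The cause of these shifts was not tested. Leaving out a library leaves the other library's value by construction, and differences between libraries have no such alternative. Both other scalings move a list and its random lists nearly alike, so they could hardly change whether a list lay beyond them. The 21 lists beyond random lists lay beyond them on the same side with both scalings, with a pseudocount of 0.1 and with the restriction to 100 reads. With a minimum of 5 RPKM, or with the trends removed, 20 did, and with a mean 19, when G2/M and TALE genes also lay below and transcription factor genes above. Erythroid genes gave no value at 5 RPKM. Lists above the central 95% by level ranged from 12 to 21, around 18, and lists below from 4 to 17, around 10. Of 148 named genes, 115 moved by more than the SD between libraries on the TPM scale, which multiplies all values. Depth limits low genes, as a count of 0 allows up to 3 reads.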

Other observations

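The 6 gene lists described first, and the genes of this part outside the naming rule, were chosen after their values were seen. Genes known to respond to low oxygen were higher in replicate 2, with a median log2 ratio of 1.76 over replicate 1 and 30 of 31 members higher, Pfkfb4 being the exception. Bnip3, a mitophagy gene, stood at 6.87 RPKM in replicate 1 and 91.3 in replicate 2, and Ak4 at 10.8 and 93.7. Macrophage genes of alternative activation had a median of 1.52 with 10 of 12 higher, among them Arg1 (arginase 1) at 9.18 and 166 RPKM, while Chil3 and Ccl24 were lower. Biosynthetic genes went the other way. Ribosome biogenesis genes had a median log2 ratio of -0.66 with all 20 lower in replicate 2, including Npm1 and Ncl. All 16 cholesterol synthesis genes with a mean of 1 RPKM or more were lower, at -0.58, including Fdps at 424 and 207 RPKM. Serine and one-carbon metabolism genes stood at -0.65 with 8 of 10 lower, including Phgdh at 164 and 69.4 RPKM, Mthfd1l and Aldh1l2 being higher. The 75 snoRNA genes stood at -0.35, with 54 lower. How well the libraries retained such short RNAs is not known, so these values may not reflect their levels.

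Among immediate early genes, Egr1 stood at 7.06 RPKM in replicate 1 and 106 in replicate 2, Fos at 18.0 and 91.0, and Junb at 17.3 and 82.7. Late neutrophil genes parted, with Retnlg at 16.6 and 169 RPKM and Mmp8 at 37.7 and 178, against Chil3 at 9447 and 3725. The precursor of ribosomal RNA, Rn45s, stood at 1283 and 2158 RPKM, and Malat1, a nuclear RNA, at 76.5 and 208. As the selection of RNA for the libraries is not stated here, the Rn45s values need not reflect its level in the cells.

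The tests of the 3 patterns that follow were chosen after the results were seen, except the correction for GC content and length, whose prediction was written before its result. Mast cell, monocyte, macrophage and MHC class II genes were all higher in replicate 2. Scaling of the libraries, which the deposited values may already carry, would move all genes alike, yet the lowest of the 4 list medians exceeded the median of all genes by 1.09. Counting error would vanish with depth, yet with members of at least 100 reads in both libraries the lowest of the 4 list medians was 1.04, above its random lists. A smaller share of the neutrophil lineage alone would raise every other type alike, but the mast cell median exceeded that of eosinophil genes by 3.88. This set the most extreme list against one of no settled direction. Neutrophil genes showed no common fall, with primary granule genes at -0.19, inside their range, and secondary granule genes at 0.19. All 8 mast cell genes were higher in replicate 2, but unevenly. Their log2 ratios included 0.31 for Slc18a2 and 0.88 for Mitf against 5.54 for Cma1 and 6.08 for Mcpt2. A larger share of mast cells, monocytes and macrophages, or a higher activity of the genes of the 4 lists, may remain. The design names no other group to test these against.

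Glycolysis genes and other hypoxia-inducible genes were higher in replicate 2. Medians of the log2 ratio in bins ran only from -0.17 to 0.11 over GC content and from -0.082 to 0.11 over transcript length. With these trends removed, the median of the hypoxia-inducible list was 1.76, against 0.11 at the upper end of its random lists. Trends this small cannot account for such a median, which argues against such a bias as the cause. The place among random lists adds nothing, as the list was chosen after values were seen. A stronger hypoxia response in replicate 2 may be an explanation, but it cannot be told apart from other states of the culture that induce the same genes, such as activation of macrophages. The 25 members in no list fixed beforehand, with a median of 1.77 and 24 higher, belong to the same list, written after some of its genes had been seen, and so give no further check. With the same trends removed, 19 of the 31 lists fixed beforehand lay above their random lists, secondary granule genes lying inside.

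Hoxa9 had at least 2 reads in replicate 1 and 176 in replicate 2, a ratio of 91.5 for the effective sizes of the libraries. The 95% interval of the ratio began at 25, so counting error does not account for it. As the series concerns cells with HOXA9 and MEIS1, an added Hoxa9 gene in some cells of replicate 2 might be a source. The other 10 Hoxa genes together had at least 13 and 122 reads, a ratio of 9.76 with a 95% interval from 5.50 to 18.9. An added gene without activity of the cluster itself would not give such a ratio. The smallest read number of each gene may fall short of the true one by its own unknown factor. The pooled ratio and its interval are therefore approximate and do not settle the point. Cells with an active Hoxa cluster stay open, with or without an added gene. Meis1, with at least 237 and 222 reads, showed no rise in replicate 2. Its ratio was 0.974 with a 95% interval from 0.807 to 1.17, which covers counting error only. The SD of 1 library was 0.37 on the log2 scale for genes from 5 RPKM, so a small added share of Meis1 could go unseen.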
